A study of Caenorhabditis elegans with 2 samples.

How the data were processed

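Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on whole Caenorhabditis elegans hermaphrodite embryos at the middle stage of embryogenesis. The worms belonged to the strain OP391, which carries a transgene that makes MED-1 with EGFP and FLAG tags at its C-terminus, together with an unc-119(+) gene that rescues the unc-119(ed3) mutation. MED-1 is a GATA-type transcription factor of the mesendoderm, the tissue that gives rise to the intestine and much of the pharynx and muscle. Per the labels, chromatin was sheared by sonication and precipitated with an antibody to GFP. A separate antibody field of the labels names med-1, the tagged protein. The series holds 1 group with 2 biological replicates, so no comparison between groups was made. The labels name a control experiment. That control and any ChIP for another factor or for GFP alone were not analysed here.

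The deposited files are peak lists in the narrowPeak format on the builds ce10 and ce11. Per the file lists deposited with the samples, the list of each replicate was made by the authors from the alignments of that replicate and a control. The pooled list was made from the alignments of both replicates and a control. These lists hold peaks and background as input for the irreproducible discovery rate (IDR), a method that keeps peaks whose ranks agree between replicates. The optimal IDR set was made from the 3 lists. The aligner, the peak caller, their versions and the IDR threshold are not given in the sources used here. The signal value of each peak is the authors' deposited signal, never negative, and serves to describe and rank peaks within a list. The q-value column holds a deposited score that is −log10 of a q-value by the format. It falls below 0 in the lists with background, so it was used as a score. The deposited summit position of each peak was used as its location. Read depth is unknown because the lists give no read counts. No error from read counting was therefore attached to a peak.

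The optimal set is the 460 strongest of the 30000 peaks in the pooled list on ce11, and the 442 strongest on ce10. IDR thus set only how many pooled peaks were kept. Analyses used ce11, which is the same assembly as WBcel235, and the peak ends lay within the chromosome lengths of the reference. The ce10 lists were used for counts, overlap and correlation within that build. No coordinates were converted. Genes and transcripts came from Ensembl release 115.

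The following choices were made before the data were examined. Replicates were compared by the share of the 460 strongest peaks of replicate 1 that overlap the 460 strongest of replicate 2 by at least 1 bp. The correlation of signal was taken across optimal peaks, which are not independent replicates. A summit was TSS-proximal when within 500 bp of the transcription start site (TSS) of a protein-coding transcript. The remaining classes, in order of priority, were coding exon, UTR, intron, non-coding RNA gene and intergenic. These shares and the overlap were tested by 100000 circular shifts, in which all peaks of a chromosome move together by a random distance. The smallest p they can give is 1e-05, one-sided. Alternatives and gene lists used 10000 shifts, with a smallest one-sided p of 0.0001. The X chromosome share was tested with a two-sided exact binomial test. A peak was assigned to the protein-coding gene with the nearest TSS within 2 kb, and 21 gene lists were tested with two-sided Fisher's exact tests and Benjamini-Hochberg adjustment over the lists. The 13 fixed motifs were searched within 100 bp of each summit and in a flank window of equal width, 300 to 500 bp from the same summit, on the left for even and on the right for odd peaks in the order of the file. Exact two-sided McNemar tests compared the windows, with Benjamini-Hochberg adjustment over the motifs. All 2080 6-mers were compared between summit and flank windows with Fisher's exact test and the same adjustment. Peaks within 20 kb of med-1 and of unc-119 were counted against windows of the same width placed every 5 kb along the chromosome.

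Genes were named by a rule. It takes the nearest gene of the 20 strongest optimal peaks, and the listed genes of mesendoderm, intestine, pharynx and muscle with a peak. It also takes the 4 strongest members of each other list, and med-1, med-2, end-1, end-3, tbx-35 and unc-119 in any case. Intervals for odds ratios given with Fisher's exact test are conditional 95% intervals. The others are exact 95% binomial intervals or are derived from them.

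Alternatives fixed before the data were examined were the ce10 lists, the 230 optimal peaks with the highest signal, other overlap rules, and the top 100, 500, 1000 or 2000 peaks. They also included other distances to the TSS, other gene assignments and backgrounds, other motif windows, dinucleotide shuffles, and other widths around the transgene genes. A further set left out peaks near the transgene genes and small RNA genes. Each replicate was left out in turn by using the 460 strongest peaks of the other. The share at small RNA genes, the peak groups, the 8-mers, the removal of mitochondrial peaks, the GC-matched background, the flank on the other side of the summit and the windows of 200 bp for motifs other than the MED site were chosen after the data were seen. The class followed through the alternatives of the feature test, coding exons, was also chosen then.

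The tests of TSS share, replicate overlap, gene lists, motifs, 6-mers and transgene windows were first run on simulated data. Other tests were not simulated. Each run held 460 peaks at random nuclear positions, or random genes for the gene lists, apart from what was planted. The random peaks had no built-in difference in GC content between summit and flank, unlike the real ones. With 40% of peaks placed at TSSs the shift test called 50 of 50 runs, and with none placed there it called 2 of 50. With 20% of peaks shared between replicates the overlap test called 50 of 50 runs, and with no shared peaks 3 of 50. With 10 ribosomal protein genes given a peak, that list was called in 50 of 50 runs. With the MED site planted in 5% of summit windows it was called in 49 of 50 runs, and with no site planted in 0 of 50. With the 6-mer GTTCGA planted in 20% of windows it ranked first in 5 of 5 runs. With 3 peaks placed within 20 kb of med-1 the window count was called in 50 of 50 runs, against 1 of 50 with none placed. Analyses were run with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Sequence matches were found with BLAST 2.17.0.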

Results

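MED-1 was mapped by anti-GFP ChIP-seq in whole mid-stage C. elegans embryos that carried MED-1-eGFP, in 2 biological replicates. The question was where in the genome the tagged factor was found. The list of replicate 1 held 2401 peaks on ce11 and that of replicate 2 held 30000, as did the pooled list, because these lists include background. The q-value column was at least 2 for 187 peaks of replicate 1, 213 of replicate 2 and 196 of the pooled list. The optimal IDR set held 460 peaks with a median width of 324 bp. The q-value column was at least 2 for 196 of them, and its lowest value was 0.0970. The signal value of all 460, as the authors' files give it, ranged from 38.9 to 778 with a median of 63.9. Read depth is unknown.

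The strongest nuclear peaks lay at the promoters of idhg-1, which encodes an isocitrate dehydrogenase subunit, and of atx-2, the ataxin-2 gene. The idhg-1 peak on chromosome III, from 4568633 to 4568870, had a signal of 521 in the optimal set, with 243 in replicate 1 and 272 in replicate 2. The atx-2 peak on III, from 10461200 to 10461412, had 415, with 217 and 198 in the replicates. K05C4.2 on I followed with 399 and C16C10.4 on III with 341. The other nuclear genes among the 20 strongest peaks were ears-2 with 303, spe-48 with 303, nmad-1 with 289, C46F11.4 with 262, B0495.9 with 261 and F39G3.3 with 253. Each of these 10 summits lay within 500 bp of a TSS. A peak with a signal of 246 lay in an intron on V, from 11314052 to 11314375, beside the snoRNA gene T03F7.8. The remaining 9 of the 20 strongest peaks were mitochondrial. The highest of all, with 778, lay in a coding exon of WBGene00010967 on the mitochondrial genome, from 12257 to 12561. The others were nearest to WBGene00010965, which had 2 peaks, WBGene00010964, WBGene00000829, WBGene00010963, WBGene00010960, ND6 and ND1. All 20 peaks ranked 39 or better in replicate 1 and 40 or better in replicate 2.

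The strongest peaks of the replicates largely coincided. Of the 460 strongest peaks of replicate 1, 305 (66.3%) overlapped one of the 460 strongest of replicate 2, against a mean of 16.6 peaks (3.61%) after circular shifts. This share was above chance (permutation p = 1e-05, one-sided, the smallest the shifts can give). Overlap was 76% for the top 100 peaks of each list and 29.6% for the top 2000. Of the 460 optimal peaks, 434 overlapped a peak in both replicates. The other 26 had no peak in the shorter list of replicate 1, and the highest of them ranked 296. Across those 434 peaks the signal of the replicates gave a Spearman rho of 0.737 and a Pearson r of 0.894, as a description across peaks.

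**Figure D1:**
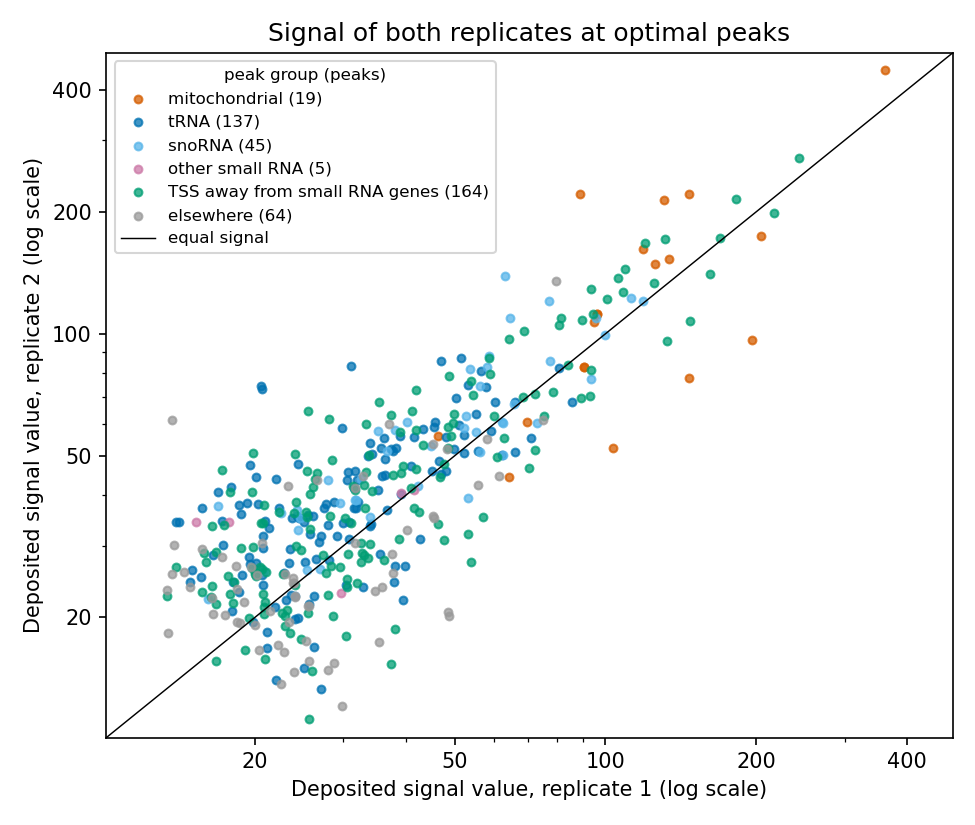
Signal value in replicate 2 (y axis, log scale) against replicate 1 (x axis, log scale), both without units, for the 434 optimal peaks with a peak in both replicates. Each point is a peak coloured by its group, and the line marks equal signal; Spearman rho was 0.737 and the median ratio of replicate 2 to replicate 1 was 1.18, and the top right point is the mitochondrial peak with 778 in the optimal set.

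Peaks were found at promoters and at non-coding RNA genes more often than by chance, and in coding exons less often. Of the 460 summits, 231 (50.2%) were TSS-proximal, against 24.8% ± 1.93 (SD over shifts), with a one-sided permutation p of 1e-05, the smallest possible. Non-coding RNA genes held 54 summits (11.7%, against 1.11%). Coding exons held 12 summits (2.61%, against 17.9%), introns 86 (18.7%, against 25.6%), UTRs 3 (0.652%, against 2.78%) and intergenic sequence 74 (16.1%, against 27.8%). The two-sided permutation p was 2e-05, the smallest possible, for coding exons, non-coding RNA genes and intergenic sequence, 0.00082 for introns and 0.0023 for UTRs.

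Many of the peaks lay at genes of small structural RNAs, a grouping chosen after the data were seen. Of all optimal summits, 203 (44.1%) were within 200 bp of a tRNA, rRNA, snRNA or snoRNA gene, against 2.51% after shifts, with a one-sided permutation p of 1e-05, the smallest possible. Among the 440 nuclear peaks, 141 (32.0%) lay at tRNA genes, against 0.303%, and 46 (10.5%) at snoRNA genes, which guide RNA modification, against 0.183%. In 85 of the 141 the summit was inside the tRNA gene. A summit lay at 151 of 612 nuclear tRNA genes (24.7%, 95% interval 21.3 to 28.3) and at 47 of 346 snoRNA genes (13.6%, 10.2 to 17.7). The corresponding counts were 6 of 129 snRNA genes, 6 of 261 miRNA genes and 0 of 20 nuclear rRNA genes (upper bound 16.8%). By comparison, 317 of 19973 nuclear protein-coding genes (1.59%, 1.42 to 1.77) had a summit within 200 bp of the gene. A further 174 nuclear peaks were TSS-proximal and away from these RNA genes, and 74 lay elsewhere in the nuclear genome.

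**Figure D2:**
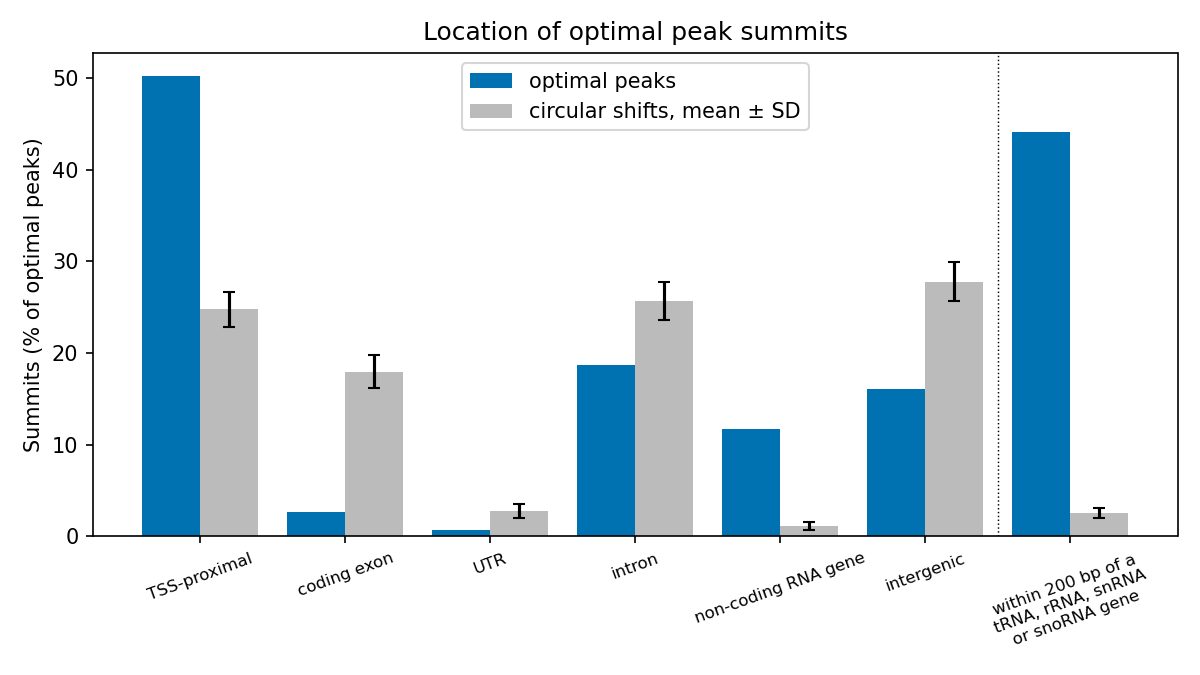
Percentage of the 460 optimal summits (y axis) in each annotation class and, right of the dotted line, within 200 bp of a tRNA, rRNA, snRNA or snoRNA gene (x axis). Blue bars are the optimal peaks and grey bars the mean of circular shifts with SD; TSS-proximal summits made up 50.2% against 24.8%, and summits at these RNA genes 44.1% against 2.51%.

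The mitochondrial genome carried 20 of the 460 peaks (4.35%). Their median signal was 193, against 64.9 for TSS-proximal nuclear peaks away from small RNA genes, 63.2 for tRNA peaks and 95.5 for snoRNA peaks. Mitochondrial peaks covered 40.7% of the mitochondrial genome, and nuclear peaks 0.139% of the nuclear genome. No MED site occurs in the mitochondrial reference sequence. The source of the mitochondrial signal was not tested, so its height is not a measure of MED-1 binding.

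The X chromosome held 23.6% of the 440 nuclear peaks (95% interval 19.7 to 27.9), above its 17.7% of nuclear length (exact binomial p = 0.00172, two-sided). Peak density was 5.87 per Mb on X, between 4.45 and 5.30 on I, II and III, and 3.20 on IV and V. Of the X peaks, 69 lay at small RNA genes, and X carries 276 of the 612 nuclear tRNA genes (45.1%). Without peaks at small RNA genes, an alternative chosen after the data were seen, X held 35 of 248 peaks (14.1%), below its share of length but not past the threshold (exact binomial p = 0.157). Peaks were found at 75 of 276 tRNA genes on X (27.2%) and at 76 of 336 on the autosomes (22.6%), a difference that did not pass Fisher's exact test (p = 0.221).

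The lists of mesendoderm, intestine, pharynx and muscle genes carried no optimal peak, and genes of the mitochondrial respiratory chain, which makes ATP, carried more than other genes. Of all genes, 356 of 19985 protein-coding genes were the nearest gene of an optimal peak. Peaks lay at 4 of 26 genes of the mitochondrial respiratory chain (15.4%, against 1.76% of other genes, odds ratio 10.1, adjusted Fisher p = 0.0114). These were nuo-2 with a signal of 51.1, cox-6B with 48.1, cox-6A with 44.0 and atp-2 with 40.5. The nuo-2 peak had no counterpart in replicate 1, and the cox-6A peak lay beside an snRNA gene. Ribosomal protein genes had 5 of 78 members with a peak (6.41%, against 1.76%, odds ratio 3.82), led by rps-28 with 98.9, rpl-3 with 89.6, rpl-35 with 62.3 and rpl-15 with 62.2. Their raw Fisher's exact p was 0.0128 and the adjusted p 0.0893. With circular shifts this list passed, with 5 members against a mean of 0.586 (ratio 8.53, adjusted permutation p = 0.0063). It missed the threshold without replicate 1 and without replicate 2 (adjusted Fisher's exact p = 0.531 and 0.0844). Over the alternatives the adjusted p ranged from 0.000283 to 0.819. Chemoreceptor genes, which act in sensory neurons, had peaks less often, at 8 of 1371 members (0.584%, against 1.87%, odds ratio 0.308, adjusted Fisher's exact p = 0.00253). The strongest were at sre-23 with 197, str-56 with 170, srd-43 with 82.7 and sri-5 with 71.5, the first 3 of them beside tRNA or snoRNA genes. This call was lost when circular shifts, which account for the space around each gene, replaced the Fisher test (adjusted permutation p = 0.854). The shifts gave a mean of 13.8 members against the 8 found, a ratio of 0.581. The call was also lost in the 230 strongest peaks, where fewer peaks were tested and the odds ratio was 0.307 (adjusted exact p = 0.225). The respiratory chain call was lost without replicate 1 (2 members, adjusted exact p = 0.544) and without replicate 2 (3 members, adjusted exact p = 0.0844), and over the alternatives its adjusted p ranged from 0.0042 to 1.

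No peak of the optimal set was nearest to any of 14 early mesendoderm genes, 29 intestine genes, 23 genes of the pharynx and MS lineage or 30 body wall muscle genes. At the rate of the shifts, 0.214, 0.440, 0.451 and 0.718 members were expected, so a lower number than by chance was not detectable for these lists. A count of 0 was also found for 37 neuronal, 32 germline, 8 Hox and posterior, 22 oxidative stress, 72 histone, 63 ceh homeobox, 31 major sperm protein and 22 heat shock genes. Among 156 collagen genes 4 had a peak, col-181, col-85, col-94 and col-185, each beside a tRNA or snRNA gene. Of 269 nuclear hormone receptor genes, nhr-255, nhr-41 and nhr-47 had one, the first pair beside tRNA genes. Single members had a peak among 32 epidermis genes (ajm-1), 240 C-type lectins (clec-126), 322 F-box genes (fbxb-58) and 33 proteasome genes (rpn-8). None of the lists in this paragraph passed Fisher's exact test, with adjusted p of 0.265 for F-box genes, 0.574 for C-type lectins and 1 for the others.

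The known targets of MED-1 were looked up in every list. Since the embryos were whole and of the middle stage alone, binding in few cells or at another stage could be missed. end-1 and end-3, which specify endoderm, and tbx-35, which specifies the MS lineage, had no optimal peak within 2 kb of the gene start. Neither did med-1, med-2 or unc-119. Of 19985 protein-coding genes, 12028 were near a peak of the pooled list with background, so such a peak near a gene was common. In that list, tbx-35 had a peak 133 bp from its start on chromosome II, with the summit at 5525530. It had a signal of 28.4, rank 1095 and −0.360 in the q-value column. Replicate 2 had a peak there with rank 1476, and replicate 1 had none. The strongest pooled peak within 2 kb of the start of med-1 ranked 505 with a signal of 37.2. For end-3 it ranked 15977, for med-2 12988 and for unc-119 24885, and end-1 had none. In replicate 2 the strongest ranked 523 for med-1, 2584 for end-3, 6366 for med-2, 14520 for unc-119 and 15471 for end-1. Replicate 1 had a peak at med-1 alone among the 6 genes, with rank 1670 and 295 bp from its start. The 1 kb upstream of the gene held 5 matches to the MED site RAGTATAC at tbx-35, 4 at end-3 and 2 at end-1.

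The MED site was no more frequent at summits than beside them. It was found in 3 of 460 summit windows (0.652%) and in 3 flank windows, an odds ratio of 1 with a 95% interval of 0.134 to 7.47 (exact McNemar p = 1). With the flank on the other side of each summit, an alternative chosen after the data were seen, 1 flank window had it (odds ratio 3, 0.241 to 157, exact p = 0.625). The summit windows with the site lay at a tRNA gene near gcy-33, at a tRNA gene near C04A11.5 and at tba-7. The interval for the share of optimal peaks with the site was 0.135% to 1.89%.

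Of the 13 fixed motifs, 9 differed between summits and flanks at an adjusted p below 0.05. The Sp1 site CCRCCC was higher at summits, found at 114 summits and 25 flanks (odds ratio 6.56, adjusted exact McNemar p = 4.11e-16), and the E2F site TTSSCGC at 70 and 20 (odds ratio 3.78, adjusted p = 3.44e-07). The forkhead site was higher, at 51 and 23 (adjusted exact p = 0.00197), as were the GA repeat, at 22 and 7 (adjusted p = 0.00883), and the promoter motif M1, at 17 and 5 (adjusted p = 0.0314). The canonical GATA site HGATAR was lower, at 152 summits and 204 flanks (odds ratio 0.631, adjusted exact p = 0.00197). The extended GATA site TGATAA was lower too, at 43 and 83 (adjusted exact p = 0.000859), as were the SKN-1 site, at 34 and 55 (adjusted p = 0.0447), and the T tract, at 68 and 93 (adjusted p = 0.0454). The E-box and the T-box site did not pass, nor did the core of the MED site. GC content was 43.3% in summit windows and 35.7% in flanks. The Sp1 site kept its call under the alternative windows, flanks and peak sets tried. The E2F site lost its call at 200 bp each side of the summit, as did both GATA sites (312 and 316 windows for HGATAR, adjusted exact p = 0.988, and 0.108 for TGATAA), the SKN-1 site, the T tract and M1. The SKN-1 site also lost it with the flank on the other side. Without replicate 1 both GATA sites, the forkhead site and the T tract also lost theirs, which left 5 motifs. The M1 call was also lost with windows of 50 bp, in the 230 strongest peaks, without replicate 2, and without peaks near the transgene genes and small RNA genes. Its odds ratio was 2 in the 230 strongest peaks and 1.93 at 200 bp. It was 3.40 in the main test, 3.33 at 50 bp, and 3.25 both without replicate 2 and without the peaks near those genes. Without those peaks the forkhead site, the GA repeat, the SKN-1 site and the T tract lost their calls too. There the odds ratio was 4 for the GA repeat, 1.92 for the forkhead site, 0.913 for the SKN-1 site and 1 for the T tract. At the 192 nuclear peaks at small RNA genes, a group chosen after the data were seen, it was 0.333 for the SKN-1 site and 0.324 for the T tract. The lower counts of these sites at summits were thus seen at small RNA genes and not away from them. The GA repeat, the SKN-1 site and the T tract also lost their calls in the 230 strongest peaks, where the GA repeat had an odds ratio of 1.75.

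**Figure D3:**
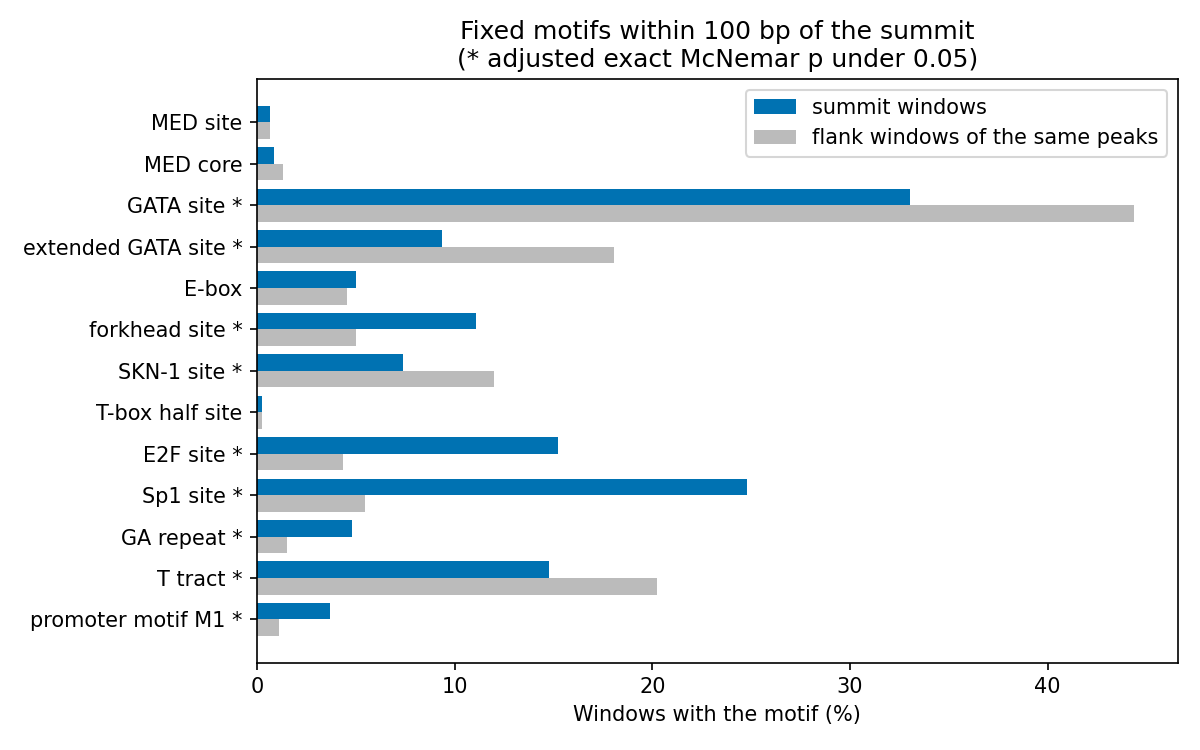
Percentage of the 460 summit windows (blue) and of flank windows of the same peaks (grey) that hold each of the 13 fixed motifs (y axis). Asterisks mark an adjusted exact McNemar p under 0.05; the Sp1 site stands at 24.8% of summits against 5.43% of flanks, and the MED site at 0.652% of both.

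In the search over all 6-mers, 345 of 2080 were more frequent at summits and 223 less frequent (Fisher's exact test, Benjamini-Hochberg adjusted p under 0.05). The 6-mer with the lowest p was GTTCGA, a sequence of the internal promoter of tRNA genes, in 143 summit windows and 31 flank windows (adjusted Fisher's exact p = 1.01e-18). This test did not use the pairing of summit and flank windows. Windows at identical tRNA gene copies are also not independent, so the p-values for 6-mers are approximate. GC-rich 6-mers followed, such as GCGCAC in 99 and 11 windows and GCGCCA in 93 and 9. The first place of GTTCGA was not kept, since the lowest p was that of CGAACC without replicate 1, GCGCAC without replicate 2, CGCGCA in the 230 strongest peaks and ACGCGC with the flank on the other side. In the 254 peaks away from small RNA genes and the transgene genes the count of higher 6-mers was 108, led by CGCACA.

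Near med-1 on the X chromosome, from 12410609 to 12451133, 3 optimal peaks were found. As many peaks occurred in 11 of 3536 windows of that width on X, a share of 0.00311. The summits were at 12423674, at 12426949 beside T24D3.2, and at 12445685, all intergenic, with signals between 44.4 and 65.1. Among the 460 strongest peaks of the single lists, the window held 6 in replicate 1 and 4 in replicate 2. Of these, only the replicate 1 peak with its summit at 12445685 overlapped peaks of replicate 2. The optimal peak at 12445685 matched peaks ranked 167 in replicate 1 and 322 in replicate 2. The one at 12423674 matched ranks 241 and 2137, and the one at 12426949 ranks 1952 and 304. For the latter pair the q-value column was 0.507 and 0.557. In the 230 optimal peaks with the highest signal the window held 1, and the share of windows with as many was 0.113. Near unc-119 on III, from 10882641 to 10928935, no optimal peak was found.

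**Figure D4:**
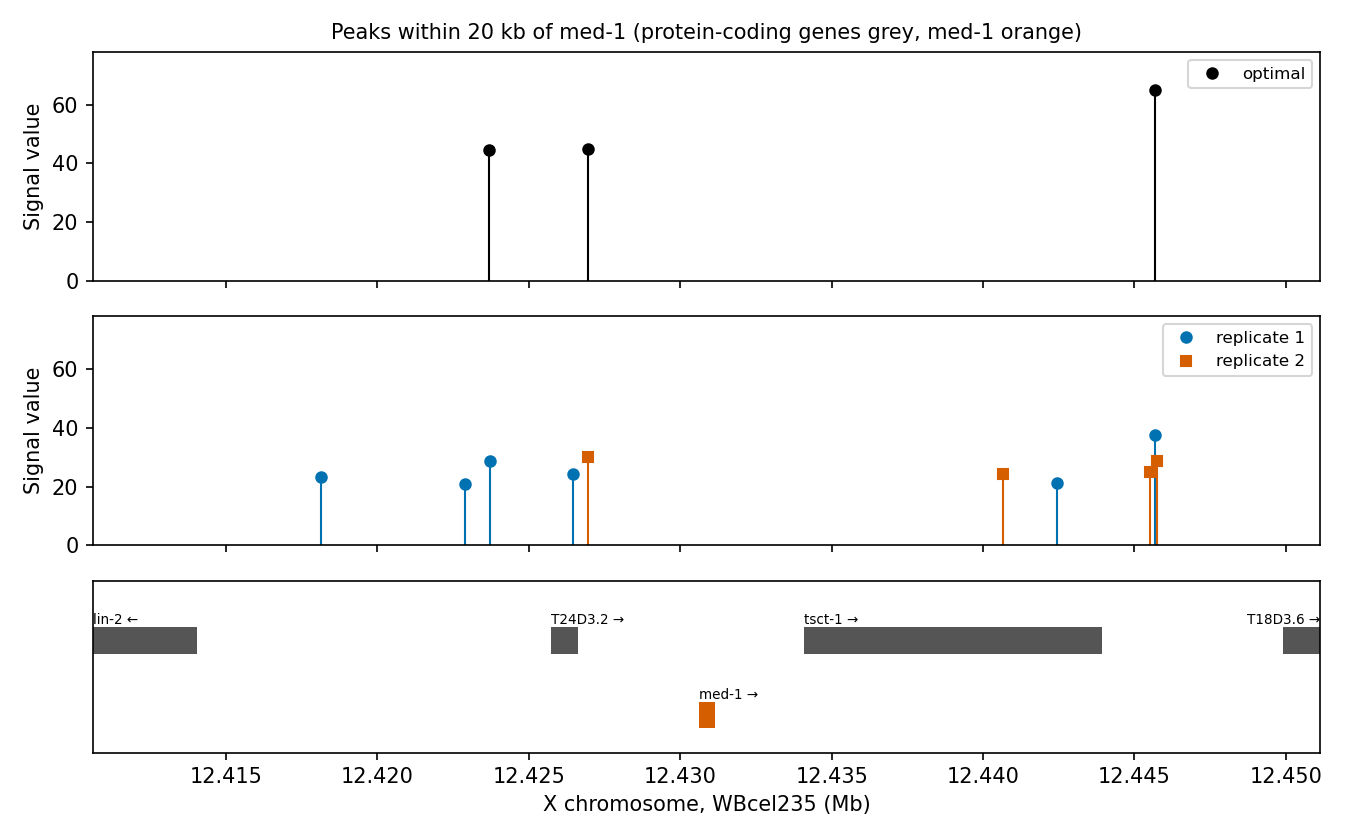
Peaks within 20 kb of med-1, by position on the X chromosome in Mb (x axis) and signal value without units (y axis). The top panel shows the 3 optimal peaks, the middle panel the peaks among the 460 strongest of replicate 1 (6) and of replicate 2 (4), and the bottom panel the protein-coding genes, with no optimal peak on med-1 itself.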

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

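The results below without mitochondrial peaks, without peaks at small RNA genes, and for 6-mers and feature classes under any alternative setting were obtained under settings chosen after the data were seen, as were the motif counts without peaks at small RNA genes, at 200 bp and with the flank on the other side. For values that answer a comparison, 66 alternative settings kept the direction and the side of the threshold or moved a count by at most 1.5 times, 14 counts moved further, 1 call ended and 1 direction turned. The TSS-proximal share stayed above its shifts under all settings, from 27.2% at 200 bp to 70.9% without peaks near the transgene genes and small RNA genes. Replicate overlap ranged from 29.6% to 76%, and rho from 0.683 in nuclear peaks away from small RNA genes to 0.737. The share of summits with the MED site ranged from 0.394% to 1.74%, and no setting brought a call. The number of peaks was 230 in the stronger set by construction, and 156 to 206 when each replicate was left out and the lowest signal of the optimal set was kept. That value is on the scale of the pooled list, where signals run higher than in a single list, so the fall follows from the scale and says nothing about dependence on a replicate. The number of gene lists past the threshold, 2 in the main test, was 0 in the stronger 230 peaks, and 1 when each replicate was left out. The respiratory chain list had 0 members in those 230 peaks; shifts of all 460 gave a mean of 0.229, so a count of 0 shows no direction. The number of motifs, 9 in the main test, was 3 at 200 bp, 5 in the stronger peaks, 4 without peaks near the transgene genes and small RNA genes, and 5 to 8 when each replicate was left out. The number of higher 6-mers, 345 in the main test, was 178 in the stronger peaks, 108 without peaks near the transgene genes and small RNA genes, and 100 in the 174 TSS-proximal peaks away from small RNA genes. For those same 174 peaks it was 185 when 870 GC-matched TSS windows replaced the flanks, a change of the kind and the number of background windows. Sets of 174, 230 and 254 peaks give these tests fewer windows, and beyond that the cause was not tested. The X share fell to 14.1% without peaks at small RNA genes, since 69 of the X peaks were at such genes. The number of peaks near med-1 was 1 in the stronger peaks, and its call ended. Among single gene lists, 180 settings stayed on their side of the threshold, 4 lost a call, 4 gained one and 1 is the count of 0 above. Among single motifs, 62 stayed and 22 lost a call. Read depth is unknown, so its part in the longer list of replicate 2 could not be examined. No paired analysis was possible because the series holds 1 group.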

Other observations

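The tests of the MED site over all optimal peaks, of GTTCGA in tRNA genes, of the peaks ranked below 1000 down to 2000 and of weaker peaks with the flank on the other side were chosen after the results were seen, as were the groups of peaks, the 8-mers and the shuffled windows for motifs other than the MED site. Counts of 8-mers picked for their frequency in these groups describe the groups, and no test compared the groups with each other. GGGTTCGA, which occurs within tRNA genes, was found at 52 of 141 tRNA peaks and 3 of their flanks, and CTGAGCTA at 46 and 1. At the 174 TSS-proximal peaks away from small RNA genes these occurred at 1 and 0 summits. There CTCCGCCC was found at 30 summits, AAACGCGC at 30 and GCCGCACA at 28, each with 0 flanks. At such peaks the Sp1 site was in 59 summit windows and 8 flanks (adjusted exact McNemar p = 2.21e-11), and the canonical GATA site in 45 and 86 (adjusted exact p = 3.25e-05).

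When each summit window was shuffled 20 times with its dinucleotide counts kept, the Sp1 site was in 11.3% of shuffled windows, against 24.8% observed. The promoter motif M1 was in 0.413%, against 3.70%, and the GA repeat in 1.07%, against 4.78%. The forkhead site was in 7.36%, against 11.1%, and the highest shuffle reached 9.78%. The E2F site was in 15.1%, against 15.2%, so its excess over flanks was not seen over shuffled windows. For the canonical GATA site the shuffled share ranged from 32.6% to 39.8% and included the observed 33.0%. The SKN-1 site and the T tract, lower at summits than in flanks, were not below their shuffled means, with 7.39% against 5.73% and 14.8% against 13.7%.

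Peaks were found at 24.7% of the nuclear tRNA genes and 13.6% of the snoRNA genes. Reads shared between identical gene copies may account for part of the tRNA peaks, since 130 of 469 genes with an identical copy and 21 of 143 single-copy genes had one (odds ratio 2.23, 95% interval 1.32 to 3.89, Fisher p = 0.00128). Identical copies are not independent, and a summit can count for several neighbouring genes, so the intervals and p-values for tRNA genes are approximate. The single-copy genes still had a peak at 14.7%, against 1.59% of nuclear protein-coding genes. How reads with several matches were treated is unknown, and other differences between single-copy and repeated tRNA genes were not tested. Reads shared with near-complete copies are argued against for the snoRNA genes. Of the 47 with a peak, 95.7% (interval 85.5 to 99.5) had no second match of at least 90% identity over 80% of the gene. Among the 299 snoRNA genes without a peak this share was 86.6%. Shorter shared stretches and the sequence beside the genes were not searched, so reads shared there are not excluded. Recognition of the MED site in or beside these genes is argued against too, since 1.04% of the 192 nuclear peaks at small RNA genes had it (upper bound 3.71%). The odds ratio for tRNA genes with GTTCGA was 1.04 (0.679 to 1.62), so the internal promoter box stays open, as do untested signal at transcribed genes regardless of the factor and recruitment of MED-1.

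Optimal peaks were frequent at promoters, but none lay within 2 kb of the start of end-1, end-3 or tbx-35. The embryos were whole and of the middle stage alone, so binding in few cells or at another stage could be missed. Binding at the MED site as the cause of most peaks is argued against, since 0.652% of the optimal peaks had the site (upper bound 1.89%). Reads shared between repeats are argued against as well, with 4.02% of the 174 TSS-proximal peaks having a second genome match (upper bound 8.11%). A general signal at open promoters of ubiquitous genes cannot be told apart from specific binding, because no ChIP for GFP alone was analysed. The odds ratio of 3.82 for ribosomal protein genes missed the threshold after adjustment (adjusted Fisher's exact p = 0.0893). With circular shifts the list passed (adjusted permutation p = 0.0063). Over the alternatives its adjusted p ranged from 0.000283 to 0.819. A call on this list does not separate general signal from specific binding either. A role of MED-1 at these promoters stays open, since the series has 1 group and no condition to compare.

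Optimal peaks clustered around med-1, with none on the gene. Extra copies of the med-1 region in the transgene are a candidate source, since a share of 0.00311 of X windows had as many optimal peaks. These windows overlap each other, so the share is not a probability. In the full set 3 peaks stood against a mean of 0.238 per window. The share was 0.113 in the 230 strongest peaks, with 1 peak against a mean of 0.117. The lists were made with a control, and whether that control carried the transgene was not examined. For unc-119, which the transgene also carries, 0 peaks and thus a share of 1 were found, but windows held 0.243 peaks on average, so extra copies of it are not excluded. The copy number and the extent of the transgene are not given in the sources used here, so regulation of the region by MED-1 stays open.

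Weaker peaks might hold the targets that the optimal set lacks. This hypothesis was tested on the nuclear peaks ranked 461 to 30000 in the pooled list. The MED site was in 213 of 29536 summit windows and in 215 flank windows, an odds ratio of 0.990 (95% interval 0.814 to 1.21, exact McNemar p = 0.961), which argues against enrichment of the site over all of them together. With the flank on the other side the odds ratio was 1.08 (0.882 to 1.32). Most of these windows, 19997, come from peaks ranked below 10000, where the odds ratio was 0.892. For ranks 461 to 1000 it was 1 (0.0127 to 78.5), with the site in 1 summit window and 1 flank window of 540. It was 2.67 (0.640 to 15.6) for ranks below 1000 down to 2000, which include the tbx-35 peak. From there it was 1.12 (0.550 to 2.29) down to 5000, and 1.25 (0.766 to 2.06) from there down to 10000. Enrichment in these parts stays open. The Sp1 site had an odds ratio of 1.29 (1.21 to 1.38) over those peaks.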
